A study of Mus musculus with 9 samples.

How the data were processed

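Small RNA was sequenced from small extracellular vesicles of mouse serum in 9 libraries. The labels place 3 libraries each in chow-fed wild-type mice (chow WT), high fat diet-fed wild-type mice (HFD WT) and high fat diet-fed mice with adipose-specific Sirt3 overexpression (HFD Sirt3 AKI). Per the labels' protocols, vesicles were precipitated from serum with a commercial reagent, pelleted and resuspended in buffer, and Illumina libraries were made. Bowtie 0.12.2 and the genome build mm8 are named, with no role, per the submitters' processing notes. Adapter trimming, the microRNA reference, the counting program and any statistical test are not given in the sources used here. A batch label separates HFD Sirt3 AKI replicates 2 and 3 from the other 7 libraries.

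The deposited tables give whole-number read counts per mature microRNA, as the authors counted them, for 1064 known microRNAs and 105 microRNAs that the files list apart as predicted. The deposited TPM table gives the same counts relative to the total of each library. Each TPM value matched the count divided by the library total, times 1000000, with a largest difference of 5.00e-05, so these values carry no length term. Counts were the basis of every result, and TPM served as an alternative. The tables of known and of predicted TPM repeat the full table and were not used here. No coordinates are given for the known microRNAs, so none are reported. A total of 9 sets of microRNAs, 18 in all, had identical counts in every library and at least 20 counts. They held 27.4% of all counts, most of them as miR-486a-5p and miR-486b-5p, whose reads cannot be assigned to one locus.

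Changes were tested in R 4.3.3 with edgeR 4.0.16. Counts were filtered with filterByExpr (minimum count 10), scaled by the trimmed mean of M values (TMM), and fitted by quasi-likelihood with group means over all 9 libraries. A microRNA was called changed at a Benjamini-Hochberg adjusted p below 0.05 over the 414 tested, of which 406 were known and 8 predicted. The 755 left out held 0.0543% of all counts. Every adjusted p given for a single microRNA comes from this edgeR test unless another tool is named. Levels are counts per 1000000 of the TMM-scaled library total (normalised CPM), as mean ± SD of 3 libraries, and errors of log2 fold changes are standard errors (SE). The mean TMM factor was 1.31 in chow WT, 0.787 in HFD WT and 0.978 in HFD Sirt3 AKI. Relative to library totals this scaling moved every log2 fold change by 0.73 in HFD WT over chow WT and by -0.31 in HFD Sirt3 AKI over HFD WT. For a group with 0 counts, a fold was given as a bound, with a floor of 3 counts over the group. Floors cover counting error only, since reads amplified without molecular identifiers are not independent molecules.

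A total of 16 lists of microRNAs were fixed before the data were examined: the miR-30 family, the let-7 family, adipose, hepatocyte, erythroid, leukocyte and platelet, endothelial, striated muscle, pancreas, brain and epithelial microRNAs, lipid metabolism regulators, inflammation and fibrosis, the miR-17 to miR-92 clusters, the Dlk1-Dio3 cluster and the Sfmbt2 cluster. Lists with at least 4 tested members were compared with all other tested microRNAs by camera of limma 3.58.1 on log2 CPM with a preset correlation of 0.01, and again with an estimated correlation. Its p-values were adjusted over the lists of one comparison. Shares of counts were compared by two-sided exact permutation tests, which cannot go below 0.1 with 3 libraries against 3. For precursors with both arms tested, the log2 ratio of the less abundant to the more abundant arm was compared between groups with limma. The named microRNAs were also set by rule before the data were examined: miR-30a-3p and its family, the 12 known microRNAs with the smallest adjusted p in each direction, abundant members of each list, those changed in both comparisons, the 10 most abundant, and up to 3 predicted ones per comparison. A few others are named because a count was small, and these were chosen after their values were seen.

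The comparison of HFD WT with chow WT and that of HFD Sirt3 AKI with HFD WT share the HFD WT libraries. Their correlation was therefore set against 100 simulated draws of groups without any difference, with each group's own spread and again with a spread shared by all groups. The edgeR and limma steps were tested on simulated counts for the 414 microRNAs, of which 200 were given a known change. In simulated HFD WT over chow WT, edgeR called 8 of 67 microRNAs at 1.5-fold, 34 of 67 at 2-fold and 54 of 66 at 4-fold, and 0 of 214 unchanged ones. In simulated HFD Sirt3 AKI over HFD WT it called 25 of 67, 42 of 67 and 56 of 66, and 8 of 214 unchanged ones. With the let-7 family simulated at a fold of 0.5, camera called it in both comparisons at either correlation. At the preset correlation camera also called 1 of 13 unshifted lists in HFD WT over chow WT, and 0 of 13 in HFD Sirt3 AKI over HFD WT. At the estimated correlation camera called 0 of 13 in either. In the simulated arm ratios of HFD WT over chow WT, 35 of 51 pairs at 4-fold were called, 0 of 51 at 2-fold and 0 of 52 unchanged ones. The simulation drew the arms of a precursor as independent. In the data, log2 differences under 2-fold were called, such as -0.91 for miR-30a and 0.82 for miR-15b. The simulated shares can therefore not be carried over to the real ratios.

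The alternatives were DESeq2 size factors, library totals, no filter, a stricter filter (10 CPM in 3 libraries), DESeq2 1.42.0, limma on log2 TPM with a pseudocount of 1 or 0.1, a fit of only the groups compared, known microRNAs only, the replicate number as a block, the batch label as a term, the larger batch alone, and each library left out in turn. Thinning all libraries at random to the smallest total, counting identical microRNAs once, and testing the lists in the larger batch alone were chosen after seeing the data.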

Results

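MicroRNAs carried by small extracellular vesicles in serum were counted in mice on chow, in wild-type mice on a high fat diet, and in mice on the same diet that overexpress Sirt3, a mitochondrial deacetylase, in adipose tissue. Each group had 3 libraries. The chow WT libraries held 306974, 293189 and 225002 counts. Those of HFD WT held 2162009, 2028235 and 1953935 counts, and those of HFD Sirt3 AKI held 2973432, 1729416 and 2109438. The mean total of HFD WT was thus 7.45 times that of chow WT. A mean of 522 ± 35.8 microRNAs was detected per chow WT library (SD, n = 3), against 709 ± 15.7 in HFD WT and 759 ± 18.1 in HFD Sirt3 AKI. The labels give separate samples but do not state separate animals, so the p-values measure only the spread between these samples. The HFD WT group is labelled wild type, while its library names carry a Sirt3 knock-in code and those of chow WT do not. A difference in mouse line between these groups can therefore not be excluded from the names. Sirt3 mRNA is not measured by this assay, so the overexpression could not be checked here.

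The spread between libraries differed by group. The biological coefficient of variation, as edgeR names it, was 10.4% in chow WT, 14.0% in HFD WT and 40.2% in HFD Sirt3 AKI. HFD Sirt3 AKI alone holds libraries of both batches, so its value also includes any difference between batches. The edgeR fit gave each microRNA a single spread for all groups. The p-values of HFD Sirt3 AKI over HFD WT therefore also rest on the chow WT libraries, which varied least. A fit of only these 2 groups, with fewer libraries, called 3 microRNAs changed, against 37 in the fit of all groups. On a multidimensional scaling of the tested microRNAs, the first dimension took 60.4% of the variance and parted chow WT from both high fat diet groups. The next took 15.1% and placed HFD Sirt3 AKI replicate 2 at 0.74, against a range of -0.28 to 0.21 in the other 8 libraries. In that library miR-122-5p, the main microRNA of hepatocytes, stood at 25960 normalised CPM, against 5679 and 11221 in replicates 1 and 3. The brain microRNA miR-9-5p stood there at 3756 against 105 and 969, and the skin and epithelial microRNA miR-203-3p at 6084 against 1259 and 2126.

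The microRNA named in the title, miR-30a-3p, was highest in chow WT serum vesicles and lowest in HFD Sirt3 AKI. Its level was 546 ± 37.3 normalised CPM in chow WT, 309 ± 17.2 in HFD WT and 206 ± 3.87 in HFD Sirt3 AKI (SD, n = 3), from 151 to 568 counts per library. It fell in HFD WT relative to chow WT, with a log2 fold change of -0.83 (SE 0.13, edgeR adjusted p = 4.52e-04). It fell further in HFD Sirt3 AKI relative to HFD WT, with a log2 fold change of -0.58 (SE 0.13, edgeR adjusted p = 0.0151). The other arm of the same precursor, miR-30a-5p, had 4979 ± 357, 5320 ± 619 and 5075 ± 900 normalised CPM in the same order, and passed the test in neither comparison (adjusted p = 0.661 and 0.799). The closely related miR-30e-3p had log2 fold changes of -0.27 (adjusted p = 0.290) and -0.40 (adjusted p = 0.173). The second decrease of miR-30a-3p was not called with the batch label as a term (-0.59, adjusted p = 0.205), in the larger batch alone (-0.45, adjusted p = 0.169) or with library totals (-0.27, adjusted p = 0.166). It was also not called without HFD WT replicate 2 (-0.58, adjusted p = 0.0724), HFD WT replicate 3 (-0.52, adjusted p = 0.136) or HFD Sirt3 AKI replicate 3 (-0.59, adjusted p = 0.0712). The call was lost as well with DESeq2 size factors (-0.48, adjusted p = 0.0569), without a filter (-0.55), in a fit of only these 2 groups (-0.45) and with limma on TPM (-0.27).

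**Figure D1:**
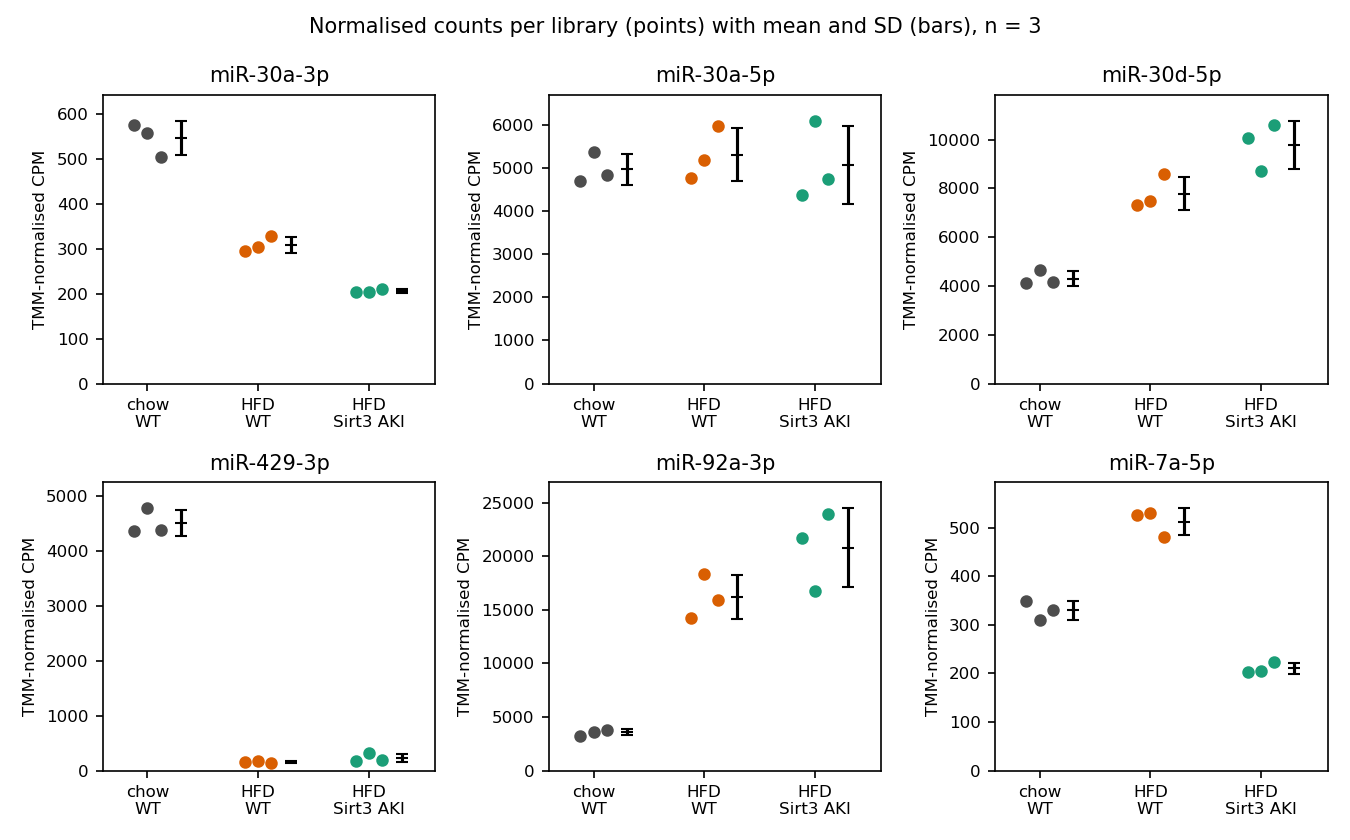
TMM-normalised CPM (y axes, linear, from 0) of 6 microRNAs in each library (points) by group, with group mean and SD (bars, n = 3). Levels of miR-30a-3p averaged 546, 309 and 206 normalised CPM in chow WT, HFD WT and HFD Sirt3 AKI, while miR-7a-5p averaged 330, 513 and 211.

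HFD WT and chow WT were compared for the effect of the diet on the vesicle microRNAs. Several members of the epithelial miR-200 family, which restrains epithelial-mesenchymal transition, fell. The level of miR-429-3p went from 4515 ± 235 to 155 ± 11.6 normalised CPM (29.2-fold, SD, n = 3; log2 fold change -4.87, SE 0.23, adjusted p = 1.80e-07), miR-200a-3p by 2.86 and miR-200b-3p by 2.18 on the log2 scale. The increase with the smallest adjusted p was in miR-92a-3p, a product of the miR-17 to miR-92 clusters that is abundant in red cells, which rose from 3569 ± 292 to 16185 ± 2064 normalised CPM (4.54-fold; log2 fold change 2.18, SE 0.16, adjusted p = 4.47e-06). The red cell microRNA miR-486a/b-5p rose by 1.47 (SE 0.12), and miR-223-3p, a myeloid microRNA that is also abundant in platelets, by 1.59 (SE 0.14). Of the 414 tested microRNAs 156 changed, 89 upward and 67 downward, and 188 had an unadjusted p below 0.05.

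The direction of the smaller changes depended on the scaling. Library totals gave 20 higher and 143 lower, and limma on TPM gave 21 higher and 156 lower, since the median log2 fold change of all tested microRNAs moved from 0.15 to -0.57 with library totals. All 67 decreases were kept with DESeq2 size factors, library totals and limma on TPM, and 66 of them with DESeq2, but each of these lowered the median log2 fold change (to 0.045, -0.57, -0.51 and 0.047). Where the values were raised instead, by 0.21 at the median without a filter, 0.12 without HFD Sirt3 AKI replicate 2 and 0.060 in the larger batch, 54 of 67, 62 of 66 and 63 of 65 decreases still tested were kept. Of the 89 increases 20 were kept with both DESeq2 size factors and library totals. These 20 include miR-92a-3p, miR-486a/b-5p, miR-223-3p, miR-215-5p, the inflammation-induced miR-146a-5p (1.45, SE 0.13), the lymphocyte microRNAs miR-150-5p (1.28, SE 0.12) and miR-342-3p (1.23, SE 0.13), and miR-99b-5p (1.51, SE 0.14). The count of changed microRNAs lay between 116 (without chow WT replicate 3) and 188 (without HFD Sirt3 AKI replicate 2) when single libraries were left out.

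Red cell microRNAs formed the only list called in this comparison. Of its 12 members 7 rose, miR-144-5p fell, and 4 did not pass, with the same counts adjusted over the list alone. The list median was 1.23, and 0.50 with library totals (camera adjusted p = 0.0089, and adjusted p = 0.68 with an estimated correlation). Its share of all counts was 40.1 ± 1.23% in chow WT and 55.6 ± 1.17% in HFD WT (SD, n = 3, exact permutation p = 0.1, the smallest possible). The members that rose were miR-486a/b-5p, miR-486a/b-3p (1.54, SE 0.15), miR-25-3p (1.37, SE 0.16), miR-92a-3p and miR-16-5p (1.08, SE 0.17), the last of which was not kept with library totals. Among the other members, miR-451a had a log2 fold change of 0.39 (adjusted p = 0.199), which was called in the larger batch (0.45) and was -0.34 with library totals, and miR-144-3p one of 0.18 (adjusted p = 0.483), which was -0.55 with library totals. The member miR-144-5p fell by 0.77 (adjusted p = 0.00453). Whether these 3 differed from the members that rose was not tested. Together miR-451a and both arms of miR-144 took 5.90 ± 0.744% of counts in chow WT and 4.54 ± 0.939% in HFD WT (exact permutation p = 0.2). With identical microRNAs counted once, the list was no longer called.

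**Figure D2:**
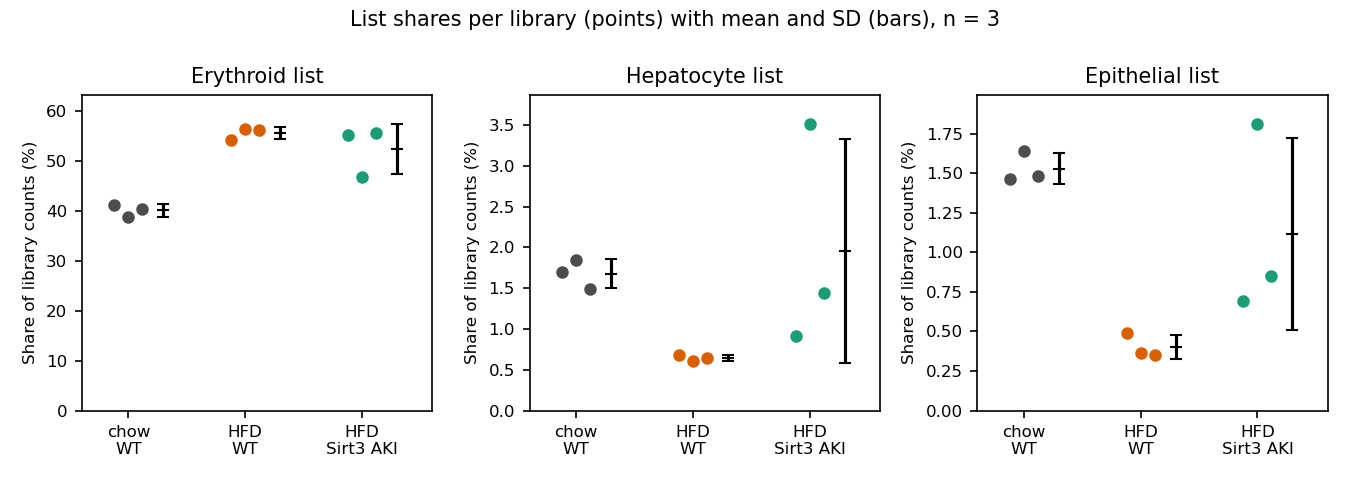
Share of all library counts in percent (y axes, from 0) taken by the erythroid, hepatocyte and epithelial lists in each library (points) by group, with group mean and SD (bars, n = 3). The erythroid share averaged 40.1% in chow WT and 55.6% in HFD WT, and the hepatocyte share averaged 0.647% in HFD WT and 1.96% in HFD Sirt3 AKI, where the libraries lay far apart.

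Epithelial microRNAs had 4 decreases and 1 increase among 10 tested members, also adjusted over the list alone (median -0.48, and -1.22 with library totals; adjusted p = 0.11). The increase was miR-205-5p, a squamous epithelial microRNA, at 0.74 (SE 0.23, adjusted p = 0.0245), which turned to -0.040 with limma on TPM. The epithelial share of counts was 1.53 ± 0.0964% in chow WT and 0.401 ± 0.0776% in HFD WT (exact permutation p = 0.1). Among 6 tested hepatocyte microRNAs 1 rose and 1 fell, with the same result adjusted over the list alone (median -0.25, and -0.98 with library totals; adjusted p = 0.79). The member that rose was miR-215-5p (2.17, SE 0.23), and miR-192-5p, from a related precursor, fell from 7198 ± 351 to 2871 ± 228 normalised CPM (-1.33, SE 0.17). The main hepatocyte microRNA miR-122-5p had 4982 ± 1571 and 4470 ± 308 normalised CPM (adjusted p = 0.813).

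Within the miR-30 family, 3 of 10 tested members fell and 1 rose, also adjusted over the list alone (median -0.45, adjusted p = 0.26), and with library totals 6 fell and 0 rose (median -1.17). Besides miR-30a-3p, miR-30b-5p fell by 0.85 (SE 0.20) and miR-30c-5p by 0.76 (SE 0.17). The abundant miR-30d-5p rose from 4300 ± 298 to 7786 ± 685 normalised CPM (0.86, SE 0.12, adjusted p = 2.09e-04). That increase was no longer called with library totals. The let-7 family, which restrains growth and insulin signalling, had 7 increases and no decrease among 10 tested members, also adjusted over the list alone. Its median of 0.50 (adjusted p = 0.11) turned to -0.23 with library totals, where 0 members rose and 3 fell, as with limma on TPM. The most abundant member, let-7i-5p, rose by 0.52 (SE 0.15), a change that was -0.21 with library totals.

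Adipose microRNAs had 4 increases and 6 decreases among 18 tested members, also adjusted over the list alone (median -0.034, adjusted p = 0.54), but 1 increase and 10 decreases with library totals (median -0.76), and 1 and 9 with limma on TPM (median -0.74). In the other direction there were 8 increases and 5 decreases without HFD Sirt3 AKI replicate 2 (median 0.080), and 8 and 6 in the larger batch (median 0.019). The median was also above 0 without chow WT replicate 1 or 2 or HFD WT replicate 1. The smooth muscle and stromal microRNA miR-145a-5p fell from 2261 ± 289 to 397 ± 149 normalised CPM (-2.51, SE 0.24). The adipogenic miR-378a-5p fell by 1.96 (SE 0.20) and miR-221-3p by 0.96 (SE 0.12). The increases were in miR-99b-5p, miR-148a-3p, miR-107-3p and miR-103-3p (0.63, SE 0.10), a regulator of insulin sensitivity that was -0.10 with library totals. Lipid metabolism regulators had 5 increases and 2 decreases among 17, also adjusted over the list alone. Their median of 0.26 (adjusted p = 0.26) turned to -0.47 with library totals, where 1 rose and 5 fell, and with limma on TPM 1 rose and 6 fell. Without HFD Sirt3 AKI replicate 2 there were 8 increases and 1 decrease, and in the larger batch 7 and 2.

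Leukocyte and platelet microRNAs had 7 increases and 2 decreases among 11 tested members, also adjusted over the list alone (median 0.39, adjusted p = 0.15), but 3 increases and 6 decreases with library totals (median -0.34) and with limma on TPM. The decreases with TMM were in miR-181a-5p and in miR-155-5p, which is induced in activated macrophages and lymphocytes and fell from 758 ± 90.3 to 231 ± 14.3 normalised CPM (-1.71, SE 0.14). Of 11 inflammation and fibrosis microRNAs 6 rose and 2 fell, also adjusted over the list alone (median 0.74, adjusted p = 0.26), and 2 rose and 2 fell with library totals (median 0.0043). The increases with TMM included miR-146a-5p, miR-214-3p and miR-21a-5p (0.79, SE 0.11). Both endothelial microRNAs tested rose, miR-126a-3p by 0.87 (SE 0.092) and miR-126a-5p by 0.99 (SE 0.11), a list too small for the set test. With library totals and with limma on TPM neither was called, and their median was 0.20 against 0.93 with TMM.

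The remaining lists were not called. The miR-17 to miR-92 clusters had 5 increases and 1 decrease among 13 (median 0.63, adjusted p = 0.12), but 2 and 3 with library totals (median -0.10). Striated muscle microRNAs had 2 increases among 5, miR-133a-3p (0.82, SE 0.12) and miR-206-3p (list median 0.24, adjusted p = 0.78), but 0 increases and 2 decreases with library totals (median -0.49). Of 3 pancreas microRNAs miR-375-3p and miR-7a-5p rose (list median 0.64, and -0.094 with library totals, where neither was called), too few for the set test. Brain microRNAs had 1 increase, miR-128-3p, which was -0.0051 with library totals, and 1 decrease, miR-219a-5p (-1.89, SE 0.29), among 7 (median -0.89, and -1.62 with library totals; adjusted p = 0.78). Counts adjusted over the list alone were the same in these 4 lists. The Dlk1-Dio3 imprinted cluster had 5 increases among 22 by edgeR and 0 adjusted over the list alone, with 6 at an unadjusted p below 0.05, 3 by DESeq2, and 0 with library totals and with limma on TPM (median 0.81, and 0.099 with library totals; adjusted p = 0.12). In the Sfmbt2 cluster miR-669c-5p alone rose among 4, and all 4 rose when adjusted over the list alone (median 1.35, and 0.63 with library totals, where no member was called; adjusted p = 0.11). Both of these clusters, but no list besides them and the erythroid one, were called with library totals at the preset correlation. Their estimated correlations were 0.50 and 0.24, with which, after TMM, the adjusted p was 0.72 and 0.68.

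Calls in the lists also moved with single libraries. The let-7 family had 4 increases without HFD WT replicate 3. Leukocyte and platelet microRNAs had 4 without any single chow WT library or HFD WT replicate 1. Inflammation and fibrosis microRNAs had 3 increases without chow WT replicate 1, chow WT replicate 3 or HFD WT replicate 2, and the miR-17 to miR-92 clusters had 3 without chow WT replicate 1. Striated muscle microRNAs had 1 increase without any single chow WT or HFD WT library or HFD Sirt3 AKI replicate 3, and pancreas microRNAs had 1 without chow WT replicate 1 or 2 or HFD WT replicate 1. The Dlk1-Dio3 cluster had 3, 2, 2 and 1 increases without HFD WT replicate 2, HFD WT replicate 1, chow WT replicate 2 and HFD WT replicate 3, and no increase was called without chow WT replicate 3. The Sfmbt2 cluster had 3 without HFD Sirt3 AKI replicate 2, and 2 without chow WT replicate 2, chow WT replicate 3 or HFD Sirt3 AKI replicate 1. The increase of miR-205-5p was the only one of the epithelial list, and no increase was called there without chow WT replicate 1, chow WT replicate 3 or HFD WT replicate 1. Without chow WT replicate 2 the medians of the hepatocyte and brain lists turned to 0.23. Brain microRNAs had 2 decreases without HFD Sirt3 AKI replicate 1 or 2, and 3 in the larger batch.

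Several scarcely studied microRNAs were far more abundant in chow WT. The level of miR-6240 was 11611 ± 670 normalised CPM in chow WT and 714 ± 153 in HFD WT (-4.02, SE 0.47), and that of miR-5126 was 473 ± 69.0 and 26.4 ± 4.96 (-4.15, SE 0.25). MicroRNAs miR-6538 and miR-203b-3p had 191 ± 18.1 and 270 ± 72.7 normalised CPM in chow WT, and 0.656 ± 0.652 and 1.98 ± 1.75 in HFD WT. All 6 predicted microRNAs that changed were lower in HFD WT. Those with the identifiers 15_11735 and 5_24224, which have identical counts, had 123 counts over the chow WT libraries and 0 over HFD WT, at least 184.6-fold lower. Predicted microRNAs took 0.0940 ± 0.0225% of chow WT counts and 0.00694 ± 8.08e-04% of HFD WT counts (exact permutation p = 0.1).

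HFD Sirt3 AKI and HFD WT were compared for the effect of adipose Sirt3 on the vesicle microRNAs under the diet. The pancreatic islet microRNA miR-375-3p rose from 182 ± 42.3 to 468 ± 70.9 normalised CPM (2.57-fold, SD, n = 3; log2 fold change 1.36, SE 0.24, adjusted p = 0.00559), and the epithelial miR-205-5p from 2600 ± 922 to 5602 ± 970 (1.11, SE 0.23, adjusted p = 0.0117). The neuroendocrine miR-7a-5p fell from 513 ± 27.5 to 211 ± 11.2 normalised CPM (-1.28, SE 0.13, adjusted p = 3.87e-04), and miR-20a-5p, a product of the miR-17 to miR-92 cluster, from 2724 ± 259 to 1114 ± 257 (-1.29, SE 0.17, adjusted p = 0.00318). Of 414 tested microRNAs 37 changed, 6 upward and 31 downward, and 109 had an unadjusted p below 0.05. The count moved with single libraries. Without HFD Sirt3 AKI replicate 1 it was 102, 55 upward and 47 downward. Without HFD Sirt3 AKI replicate 2 it was 51, 17 upward and 34 downward, and without HFD Sirt3 AKI replicate 3 it was 19. Without HFD WT replicates 1, 2 and 3 in turn it was 23, 17 and 13, and without chow WT replicate 1 or 2 it was 24.

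The other increases were in miR-122-5p (1.68, SE 0.44), miR-615-3p (1.64, SE 0.35), miR-99a-5p (0.62, SE 0.15) and miR-222-3p (0.52, SE 0.15). The increase of miR-122-5p, from 4470 ± 308 to 14287 ± 10482 normalised CPM, moved with HFD Sirt3 AKI replicate 2, the library that stood apart, and was 0.93 (adjusted p = 0.0135) without that library and 0.48 (adjusted p = 0.198) in the larger batch, where replicate 1 is the only Sirt3 AKI library. The red cell microRNAs miR-144-5p and miR-144-3p fell by 1.21 (SE 0.17) and 1.19 (SE 0.18). Further decreases were in miR-17-5p (-1.05, SE 0.18), miR-186-5p (-0.84, SE 0.14), miR-93-5p (-0.84, SE 0.15), miR-185-5p (-0.79, SE 0.13), a regulator of cholesterol uptake, and miR-148b-3p (-0.74, SE 0.14).

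The share of increases depended on the processing. There were 10 higher and 14 lower with DESeq2 size factors, 36 and 11 with library totals, 29 and 11 with limma on TPM, 33 and 22 without a filter, and 38 and 27 with DESeq2. DESeq2 left 121 of the 414 microRNAs without an adjusted p in this comparison. Under all of TMM, DESeq2 size factors and library totals 6 increases and 11 decreases were kept, among them miR-7a-5p, miR-20a-5p, both arms of miR-144, miR-17-5p, miR-93-5p, miR-185-5p, miR-186-5p and let-7d-5p. Both other scalings raised the median log2 fold change, from -0.021 to 0.060 and 0.27, so keeping the increases was to be expected. Batch and group overlap: with batch as a term 1 call remained, miR-7a-5p (-1.33, adjusted p = 0.0110). In the larger batch, with the lone Sirt3 AKI library assumed to vary like the other groups, 10 of the 37 were kept. These were miR-375-3p (1.57), miR-205-5p (1.00), miR-222-3p (0.76), miR-7a-5p (-1.19), miR-20a-5p (-0.83), miR-144-3p (-0.94), miR-144-5p (-0.73), miR-17-5p (-0.82), miR-93-5p (-0.54) and miR-186-5p (-0.51). The smaller batch holds Sirt3 AKI libraries only and gives no value. A fit of only these 2 groups called miR-7a-5p, miR-375-3p and miR-20a-5p.

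The let-7 family had 6 decreases among 10 tested members, and 9 adjusted over the list alone. With DESeq2 size factors and with library totals 2 decreases were called, and in the larger batch 0. Its median was -0.49 (camera adjusted p = 1.56e-05, and adjusted p = 0.46 with an estimated correlation), -0.17 with library totals and -0.25 in the larger batch. The larger batch, with 1 Sirt3 AKI library, was tested at the preset correlation only, and the list was called there. With all libraries the fall was -0.73 (SE 0.12) in let-7d-5p, from 5930 ± 230 to 3569 ± 477 normalised CPM, and -0.66 (SE 0.15) in let-7i-5p. The miR-17 to miR-92 clusters, which promote cell growth, had 4 decreases among 13, and 7 adjusted over the list alone (median -0.71, adjusted p = 6.83e-04, and adjusted p = 0.55 with an estimated correlation). With library totals (median -0.41) and in the larger batch (median -0.49) there were 3 decreases and 1 increase, miR-92a-3p. Red cell microRNAs had 5 decreases among 12, and 6 adjusted over the list alone (median -0.46, adjusted p = 7.03e-04, and adjusted p = 0.55 with an estimated correlation). There were 2 decreases with DESeq2 size factors, and 2 decreases and 1 increase, miR-92a-3p, both with library totals (median -0.15) and in the larger batch (median -0.13). Without HFD Sirt3 AKI replicate 2 there were 3 decreases and 1 increase (median -0.26, list adjusted p = 0.042). Among these microRNAs, miR-451a fell by 0.83 (SE 0.22, adjusted p = 0.0488), while the erythroid share of counts was 52.5 ± 4.99% against 55.6 ± 1.17% in HFD WT (exact permutation p = 0.5).

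Epithelial microRNAs were shifted upward, with 1 increase among 10, miR-205-5p, and 9 adjusted over the list alone (median 1.08, adjusted p = 2.24e-04, and adjusted p = 0.55 with an estimated correlation). With library totals 4 were called as increases. The list moved with HFD Sirt3 AKI replicate 2: miR-203-3p had 3156 ± 2572 and miR-200a-3p 941 ± 694 normalised CPM, against 1172 ± 124 and 421 ± 34.7 in HFD WT. Its median was 0.26 in the larger batch. Hepatocyte microRNAs had 1 increase among 6, miR-122-5p, also adjusted over the list alone (median 0.48, adjusted p = 0.048, and adjusted p = 0.55 with an estimated correlation), and took 1.96 ± 1.38% of counts against 0.647 ± 0.0347% in HFD WT (exact permutation p = 0.1). The Dlk1-Dio3 cluster had 0 changes among 22 by edgeR, also adjusted over the list alone, with 4 increases at an unadjusted p below 0.05, 1 by DESeq2 and 0 by limma on TPM. It was shifted upward as a list (median 0.69, and -0.25 in the larger batch; adjusted p = 0.014, and adjusted p = 0.55 with an estimated correlation). Its most abundant member miR-127-3p stood at 641 normalised CPM in HFD Sirt3 AKI replicate 2 and at 127 and 280 in replicates 1 and 3. Of these 6 lists only the let-7 family was called with batch as a term or in the larger batch. Both were run at the preset correlation only. In both, 1 Sirt3 AKI library carries the group difference, so that call does not measure the spread between Sirt3 AKI samples. Without HFD Sirt3 AKI replicate 2, the hepatocyte and Dlk1-Dio3 lists were no longer called and 4 lists remained.

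Both endothelial microRNAs tested fell, miR-126a-3p by 0.51 (SE 0.092) and miR-126a-5p by 0.68 (SE 0.11). They were at -0.35 (adjusted p = 0.0882) and -0.47 (adjusted p = 0.0628) in the larger batch, and with library totals neither was called and their median was -0.28 against -0.60. Counts adjusted over the list alone were the same in the remaining lists unless given. Brain microRNAs had 0 changes among 7 by edgeR, and 2 increases adjusted over the list alone, with 4 at an unadjusted p below 0.05, 3 by DESeq2 and 1 by limma on TPM (median 0.82, and -0.50 in the larger batch; adjusted p = 0.24). Of 3 pancreas microRNAs miR-375-3p rose, miR-7a-5p fell and miR-7b-5p did not pass (-1.10). Without HFD Sirt3 AKI replicate 2, miR-7b-5p was called as a decrease (-2.52, adjusted p = 2.60e-04), and it was -2.42 in the larger batch. Adipose microRNAs had 1 increase, miR-222-3p, and 1 decrease, miR-107-3p, among 18 (median 0.23, and -0.12 with batch as a term; adjusted p = 0.26), and 3 increases and 0 decreases with library totals (median 0.58). The miR-30 family had 1 decrease, miR-30a-3p, among 10 (median -0.12, adjusted p = 0.79), but 1 increase, miR-30d-5p, and 0 decreases with library totals (median 0.20), with limma on TPM and in the larger batch (miR-30d-5p 0.51, adjusted p = 0.0190).

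Leukocyte and platelet microRNAs had 1 decrease, miR-142a-3p, among 11, and 1 increase and 1 decrease adjusted over the list alone (median -0.074, adjusted p = 0.82), but 3 increases and 0 decreases with library totals (median 0.23) and with limma on TPM. Lipid metabolism regulators had 1 increase and 3 decreases among 17, and 1 and 4 adjusted over the list alone (median -0.17, and 0.16 with library totals; adjusted p = 0.34). Inflammation and fibrosis microRNAs had 0 changes among 11 by edgeR, DESeq2 and limma on TPM, with 1 higher and 1 lower at an unadjusted p below 0.05 (median -0.056 with an upward test direction, and 0.25 with library totals; adjusted p = 0.96). Striated muscle microRNAs had 0 changes among 5 by all 3 tools and 0 at an unadjusted p below 0.05 (median -0.22, and 0.14 with library totals; adjusted p = 0.31), but 2 decreases without HFD Sirt3 AKI replicate 2 (median -0.42) and 1 in the larger batch (median -0.47). The Sfmbt2 cluster had 0 changes among 4 by all 3 tools, and 1 decrease adjusted over the list alone, the only one at an unadjusted p below 0.05 (median -0.19, and 0.11 with library totals; adjusted p = 0.34).

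Single libraries moved the calls in these lists as well. Without HFD Sirt3 AKI replicate 1, the only library of that group in the larger batch, 9 epithelial, 10 Dlk1-Dio3, 6 lipid, 5 adipose, 4 hepatocyte, 4 brain and 3 inflammation and fibrosis microRNAs were called as increases, and the brain list was called too (adjusted p = 0.027). The Sfmbt2 cluster then had 1 decrease, and leukocyte and platelet microRNAs had 1 increase and 2 decreases. The let-7 family had 3 decreases without HFD WT replicate 1 or HFD Sirt3 AKI replicate 3, 2 without HFD WT replicate 2 and 1 without HFD WT replicate 3. Red cell microRNAs had 3 decreases without HFD WT replicate 1, and 2 without any single chow WT library, HFD WT replicate 2, HFD WT replicate 3 or HFD Sirt3 AKI replicate 3. No epithelial increase was called without HFD WT replicate 2 or 3, and no hepatocyte increase without chow WT replicate 1 or 2, any single HFD WT library or HFD Sirt3 AKI replicate 3. No adipose call was left without any single chow WT library, HFD WT replicate 2, HFD WT replicate 3 or HFD Sirt3 AKI replicate 3. Without HFD Sirt3 AKI replicate 2, leukocyte and platelet microRNAs had 3 increases and 1 decrease (median 0.077).

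The comparisons were set side by side to see whether adipose Sirt3 moved the microRNAs that differed with the diet. Of the microRNAs that changed in both, 17 rose in HFD WT and fell in HFD Sirt3 AKI, where 6.66 would be shared by independent lists. They include miR-7a-5p, miR-20a-5p, miR-93-5p, both arms of miR-126a, let-7b-5p, let-7d-5p, let-7g-5p and let-7i-5p, miR-107-3p and miR-142a-3p. With library totals the diet increase of miR-7a-5p (-0.094), miR-20a-5p (-0.10), let-7d-5p (-0.024), let-7b-5p (-0.22), let-7i-5p (-0.21) and miR-142a-3p (-0.38) was turned. Of the 17, only miR-423-5p and miR-486a/b-3p kept their diet increase with both DESeq2 size factors and library totals. Their decrease in HFD Sirt3 AKI was not kept, so none of the 17 was kept in both comparisons. Relative to library totals, TMM moves the comparisons by 0.73 and -0.31, in the directions of this pattern. The Hox cluster microRNA miR-615-3p fell with the diet, from 25.5 ± 4.86 to 5.48 ± 1.52 normalised CPM, and rose to 17.5 ± 3.67 in HFD Sirt3 AKI. Both changes of miR-615-3p were kept under these scalings. Its increase in HFD Sirt3 AKI was not called in the larger batch (1.60) or with batch as a term (1.47). Another 6 changed in the same direction in both comparisons: miR-205-5p and miR-375-3p rose, and miR-30a-3p, miR-10a-3p, miR-144-5p and miR-301a-3p fell. Independent lists would share 1.29 and 5.02. Instead of 6, the count was 12, 15 and 3 without HFD Sirt3 AKI replicates 1, 2 and 3 in turn, and 12 with DESeq2. It was 2 or 3 without any single chow WT or HFD WT library. Of the 6 named, only miR-144-5p kept both calls with DESeq2 size factors and library totals. The diet increases of miR-205-5p and miR-375-3p were not kept. Neither were the decreases of miR-30a-3p, miR-10a-3p and miR-301a-3p in HFD Sirt3 AKI.

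**Figure D3:**
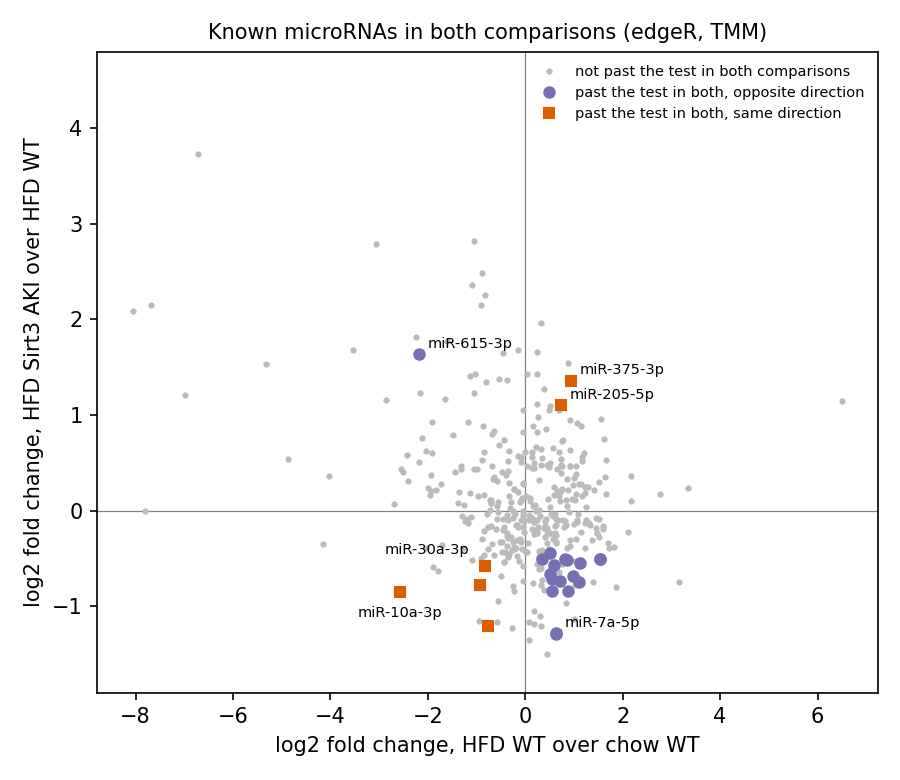
Log2 fold change of each known tested microRNA in HFD WT over chow WT (x axis) and in HFD Sirt3 AKI over HFD WT (y axis), marked by whether it passed the test in both comparisons and in which directions. Among those that passed in both, 18 lie in opposite directions and 6, miR-30a-3p among them, in the same direction.

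Across the 414 microRNAs, which are not independent replicates, the log2 fold changes of the comparisons had a Pearson r of -0.29 and a covariance of -0.375. In the simulated groups without differences, r averaged -0.21 (SD 0.074, range -0.48 to -0.036) and the covariance averaged -0.0459, with each group's own spread. With a spread shared by all groups r averaged -0.39 (range -0.54 to -0.19) and the covariance -0.106. The observed r lay within both ranges, stronger than the first mean and weaker than the second, so r alone does not part the groups from groups without differences. The observed covariance lay beyond every draw and differed from the simulated means by -0.329 and -0.269. The simulated ranges were -0.110 to -0.00915 with each group's own spread and -0.170 to -0.0485 with the shared spread. The draws took microRNAs as independent and gave each its mean over all libraries. The estimated correlation in the epithelial list, however, was 0.70, so these ranges may be too narrow. They cannot show that the covariance exceeds what shared controls give. The observed covariance also depended on the processing. With library totals it was -0.327, and with limma on TPM -0.278 at a pseudocount of 0.1 but -0.122 at 1. With only the groups compared in each fit it was -0.136. The last 2 values lie within the range of the shared spread, which was drawn for the main fit. With batch as a term r was -0.097 and the covariance -0.108, and in the larger batch alone -0.088 and -0.108. These values of r are weaker than both simulated means, and those covariances lie within both simulated ranges, which were drawn for all 9 libraries without batches. The 18 opposite changes could not be gauged against these draws, which gave too few calls. HFD WT has 3 libraries and could not be divided between the comparisons, so part of the opposite changes may come from the shared controls. With batch as a term 1 microRNA was called in opposite directions, in the larger batch alone 8, and with DESeq2 size factors 7. In the larger batch, where 1 Sirt3 AKI library is left, same-direction changes outnumbered the opposite ones. Opposite changes numbered 18 with library totals and 24 with DESeq2. Leaving out HFD Sirt3 AKI replicate 1 gave 37, replicate 2 gave 23 and replicate 3 gave 11. Leaving out HFD WT replicates 1, 2 and 3 in turn gave 11, 8 and 4, and chow WT replicates 1, 2 and 3 gave 8, 9 and 8.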

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

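Thinning, counting identical microRNAs once and testing the lists in the larger batch alone were chosen after the data were seen; the other alternatives were fixed before the data were examined. In HFD WT over chow WT, miR-30a-3p kept its decrease and its call under every alternative, with -0.88 to -0.71 when single libraries were left out (highest adjusted p = 0.00493). The count of changed microRNAs ranged from 116 to 188 without single libraries. In HFD Sirt3 AKI over HFD WT it ranged from 13 (without HFD WT replicate 3) to 102 (without HFD Sirt3 AKI replicate 1), and opposite changes ranged from 4 to 37 without the same libraries. From 13 to 36 of the 37 calls were kept, and all 37 kept their sign where tested. The r ranged from -0.35 to -0.20, the lists called from 1 to 2 (the second without chow WT replicate 3) and from 4 to 7, and the second decrease of miR-30a-3p from -0.62 to -0.52. It was not called without HFD WT replicate 2, HFD WT replicate 3 or HFD Sirt3 AKI replicate 3, with fewer libraries in the fit.

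Elsewhere the cause was not tested unless stated. DESeq2 size factors gave 24 changed microRNAs in HFD Sirt3 AKI over HFD WT, 7 opposite changes and -0.48 for miR-30a-3p (adjusted p = 0.0569). DESeq2 gave 65 changed, with 121 of the 414 microRNAs left without an adjusted p. The log2 fold change of miR-30a-3p was -0.27 with library totals and with limma on TPM at either pseudocount, which the scaling itself moves, and -0.55 without a filter (adjusted p = 0.109), where 1169 microRNAs were tested. A fit of only the 2 groups left 3 changed and -0.45 for miR-30a-3p (adjusted p = 0.107). With batch as a term 1 microRNA changed, 1 was opposite, r was -0.097, 1 list was called and miR-30a-3p was at -0.59. That term leaves 1 Sirt3 AKI library to carry the group difference. The larger batch gave 23 changed, 8 opposite, r of -0.088, 1 list and -0.45 for miR-30a-3p. With limma on TPM and a pseudocount of 1, r was -0.15. With an estimated correlation 0 lists were called in either comparison. In HFD WT over chow WT library totals called 3 lists, and counting identical microRNAs once called 0, since miR-486a and miR-486b are then single members. The erythroid share was then 35.0%, 48.9% and 45.0% in chow WT, HFD WT and HFD Sirt3 AKI, and 5.90%, 4.54% and 3.14% from miR-451a and miR-144 alone.

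Log2 fold changes of HFD WT over chow WT that turned negative with library totals, which remove the TMM shift of 0.73, were also negative with limma on TPM at both pseudocounts: miR-30a-5p (-0.64), miR-30e-5p (-0.59), miR-99a-5p (-0.60), miR-7a-5p (-0.094 and -0.096), miR-20a-5p (-0.10 and -0.095), let-7d-5p (-0.024 and -0.025), miR-17-5p (-0.56), let-7i-5p (-0.21), let-7a-5p (-0.49), let-7c-5p (-0.29), miR-103-3p (-0.10), miR-191-5p (-0.34), miR-142a-3p (-0.38), miR-206-3p (-0.29), miR-128-3p (-0.0051 and -0.0057), miR-29a-3p (-0.17) and let-7b-5p (-0.22). With limma on TPM miR-205-5p (-0.040) and miR-144-3p (-0.55 and -0.56) were negative too. In HFD Sirt3 AKI over HFD WT, miR-6240 was -1.02 in the larger batch (adjusted p = 0.00212). Replicate numbers did not pair the libraries: correlations of deviations ran from -0.080 to 0.19 for the same number and from -0.22 to 0.15 for different numbers. The replicate number as a block gave 154 and 31 changed microRNAs and 14 opposite changes.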

Other observations

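The arm ratios, the thinning, the summed counts of the miR-30a and miR-30e arms, the raising of the decreases, and the shares of calls kept in this part are tests chosen after the results were seen. The ratio of both arms of a precursor does not depend on the scaling of a library, apart from the pseudocount of 1 TPM added to each arm. That pseudocount and the low totals of chow WT weigh on scarce arms. The arm miR-139-3p, for example, averaged 19.8 TPM, and its log2 ratio had an SD of 2.00 in chow WT. In HFD WT relative to chow WT, limma called this ratio lower for the less abundant arm in 22 of 102 precursors and higher in 15, with 41 at an unadjusted p below 0.05. Among the 27 precursors whose less abundant arm averaged at least 50 TPM, 12 were lower and 5 higher. The passenger arm let-7d-3p fell by 2.07 on the log2 scale relative to let-7d-5p (SE 0.20, adjusted p = 2.78e-04), and miR-99b-3p by 2.51 (SE 0.25) relative to miR-99b-5p. The Hox cluster microRNAs miR-10a-3p and miR-10b-3p fell relative to their 5p arms by 2.02 (SE 0.23) and 1.88 (SE 0.19), and the adipogenic miR-378a-5p relative to miR-378a-3p by 1.49 (SE 0.23). In the other direction miR-17-5p rose relative to miR-17-3p by 1.42 (SE 0.21) and miR-144-3p relative to miR-144-5p by 0.95 (SE 0.21). In HFD Sirt3 AKI relative to HFD WT limma called 0 ratios, with 16 at an unadjusted p below 0.05. Other tools were not run on the ratios.

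In HFD WT over chow WT the arm ratio of miR-30a-3p to miR-30a-5p was at -0.91 (SE 0.21, limma adjusted p = 0.00994). The scaling between libraries can therefore not be the cause of the difference between the arms. Whether miR-30a-3p fell or miR-30a-5p rose does depend on the scaling. When raised by 0.73, miR-30a-3p no longer stayed more than 2 SE below 0, so scaling stays open for the decrease itself. Thinning every library to the depth of the shallowest left -0.90 and the call, which argues against depth alone. The summed counts of miR-30a-3p and miR-30e-3p, whose sequences are close, were at -0.67 (SE 0.13, adjusted p = 0.00184), so reads moved between the 2 cannot account for it. A response to the diet is a candidate explanation. A difference in the quality or amount of RNA in the chow WT libraries, and one in mouse line, stay open and were not tested.

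Most of the diet calls may not rest on depth alone: 78.9% of those still tested kept direction and call after thinning. These were 53 of 54 decreases and 52 of 79 increases, so thinning told mainly on the increases, and the thinned libraries gave 52 higher and 68 lower. Thinning also moved the log2 fold changes by -0.17 at the median, so keeping more of the decreases than of the increases was to be expected. A scaling moves all microRNAs alike. When the decreases were raised by 0.73 on the log2 scale, as far as library totals lowered them, 62.7% (42 of 67) stayed more than 2 SE below 0, so a scaling of that size cannot be the cause of these. Of the remaining 25 decreases, miR-30a-3p among them, 32% turned to increases. For these 25 a real decrease and an effect of scaling cannot be told apart. A larger scaling error was not tested. Of the increases 22.5% were kept with library totals, and for the others a real increase and an effect of scaling cannot be told apart, because no measure of the absolute amount of vesicle RNA was used here. The lower share of predicted microRNAs in HFD WT, and the fall of miR-6240 and miR-5126, could reflect a different make-up of the chow WT libraries, which thinning does not test. The diet stays among the open explanations.

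For the Sirt3 AKI calls, 89.2% were kept without replicate 2, the library with high liver, brain and epithelial microRNAs, which argues against that library as their only source. In the larger batch 27.0% were kept, so batch and an effect of adipose Sirt3 cannot be told apart for the remaining calls: the batches differ in 2 of the 3 Sirt3 AKI libraries and 1 is left for the comparison. The calls kept there rest on that 1 library, from the group with the largest spread (40.2%, against 10.4% in chow WT and 14.0% in HFD WT). That spread includes any difference between the batches. For the calls kept there, an effect of adipose Sirt3 and variation between samples cannot be told apart either. These calls, among them miR-7a-5p, miR-375-3p and miR-20a-5p, may be the ones to measure again.

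Other splits of the same 6 libraries into 3 against 3 were also fitted. The real split gave 156 changed microRNAs for diet and the highest other split 0. For Sirt3 AKI these were 37 and 1, and for opposite changes 18 and 1. In each case 1 of the 10 splits, the real one, gave as large a value. For the lists, 4 of 10 splits gave as many as the real one in either comparison. In HFD WT and chow WT the real split called 1 list and the highest other 3. In HFD Sirt3 AKI and HFD WT it called 6, and the split that exchanged HFD Sirt3 AKI replicate 1 and HFD WT replicate 3 called 7, which points to a structure among the Sirt3 AKI libraries, replicates 2 and 3 of which share a batch. With 10 splits no share under 0.05 can be reached.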
